A study of Mus musculus with 8 samples.

How the data were processed

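Gene expression was measured in 8 samples of NMuMG-NT2197 cells on Agilent two-colour arrays, 4 with ShcA R175Q and 4 with wild-type ShcA. Per the labels, 1 to 2.5 ng of RNA went through 2 rounds of linear amplification, and 5 µg of labelled RNA in Cy3 was hybridized with a Cy5 reference. The labels call the reference mouse in 1 field and human in the labelling protocol, and they call the material microdissected although they describe cultured cells. Neither conflict could be settled.

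Per the file headers, Agilent Feature Extraction 9.5.3.1 wrote the mean intensity of each spot, the median intensity of its local background, processed signals after dye normalization, and a log10 ratio of processed Cy5 over Cy3. The deposited value table holds log2 ratios of Cy3 over Cy5, as judged from its values: against the scanner's ratio, turned to the same direction, Pearson's r across probes was 0.902 to 0.941 and the slope 0.657 to 0.751. Genes are not independent replicates in such an r. How the authors scaled and centred that table is not stated. Its column medians were 0.0585, 0.0563, 0.0607 and 0.0544 for R175Q replicates 1 to 4 and 0.0526, 0.0617, 0.0592 and 0.0556 for wild-type replicates 1 to 4.

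Each array held 44397 spots, of which 1377 were controls, including 153 negative control spots, and 43020 were not. The spot intensities were used as the starting values. Background was corrected by normexp with an offset of 50 on mean signals and median local backgrounds, followed by loess within each array, in limma 3.58.1 (statmod 1.5.0, R 4.3.3). Values are log2 of Cy3 over Cy5. Spots of a probe were averaged, giving 39429 probes. Probes were kept if well above background in Cy3 on at least 4 of the 8 arrays, which 22971 were; 122 with a value that the scanner software marked as unreliable on some array were left out. Of the 22849 left, the brightest probe of each gene was used, giving 17458 genes, 12941 of them with a symbol.

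Gene names came from the files. For 26761 of 28389 probes with a RefSeq accession, a table of the GRCm38.p6 annotation gave the current symbol, which changed 2878 symbols; that table was used for names only. Coordinates are those of the files, in mm9. No genome or gene model was used to place probes in exons or UTRs.

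Samples were grouped by the labels. The single comparison, R175Q less wild type, used limma's moderated test (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Values after ± are standard errors of the difference unless named SD. The 25 lists, 17 gene lists and 8 lists of cell type markers, were tested with camera at its preset correlation, with camera at an estimated correlation, with fry, and with an exact two-sided permutation test of the mean per array over 70 assignments, each adjusted over the lists. Slide 1 held 1 array, so within-slide values come from the other 3 slides.

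The comparison, filters, lists and the alternatives were fixed before the data were examined. Named genes were Shc1, Erbb2, Fn1, Itga5 and Itgb1, then up to 15 genes in each direction with the largest change among those past the threshold, changed by at least 1 log2, with a symbol and groups that did not overlap (30 genes higher and 13 lower met this), then up to 4 members of each list with the lowest unadjusted p. Ccl8, Ifit2, Nid1, Mrc1, Adgre1, Dcn, Col3a1, Tgfa, Zeb1, S100a4, Foxc2, Vwf, Krt17, Hba-a1 and Hba-a2, the members that each list added with the negative control background, and any other list member named outside that rule, were chosen after their values were seen.

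The alternatives were no background correction, the scanner's processed ratio, median centring in place of loess, quantile normalization of brightness, scaling between arrays, the Cy3 channel alone, the deposited table, no filter, a filter on all 8 arrays, every probe on its own, the mean of a gene's probes, eBayes with a trend and robust fit, arrayWeights, replicate number, slide as a fixed or random block, and leaving out each array. The background from negative control spots, alone and with slide as a fixed block, and scan day as a fixed block were added after seeing the data.

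The procedure was tested on simulated data with known changes. It recovered 70% of genes changed by 0.5 log2, 86% at 1, 94% at 1.5 and 96% at 2, with 7.49% false calls. With the negative control background these were 68%, 98%, 100% and 100%, with 3.68% false calls. A list raised by 0.5 was called, and 0 of 24 unchanged lists were. In the simulation genes varied independently of each other, with no effects of array, slide or background. Its rates therefore do not cover such effects or lists of correlated genes, such as the interferon response list with an estimated correlation of 0.36. Precision is limited by the number of arrays. Nothing among the 8 arrays was left out.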

Results

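RNA from 8 samples of NMuMG-NT2197, a derivative of the NMuMG mouse mammary epithelial line, was measured on 8 two-colour Agilent arrays. In 4 samples the cells carried a cDNA of wild-type ShcA, an adaptor protein that docks on activated receptor tyrosine kinases. In 4 they carried ShcA R175Q, in which glutamine replaces arginine in the PTB domain, a part that binds phosphotyrosine. Each array held 1 sample in Cy3 and a common reference RNA in Cy5, with no exchange of dyes, so every value is a log2 ratio of sample over reference. Between 53.7% and 63.0% of spots stood well above background in Cy3 and between 61.1% and 71.7% in Cy5, and no spot was saturated. The number of arrays, 4 per group, limits the precision. The labels do not state whether the replicates of a group have separate origins, so each p measures only the spread between these samples.

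The comparison asked which transcripts differ between cells with the R175Q form and cells with wild-type ShcA. The largest rises in R175Q were those of Csf2rb, the signalling subunit of the GM-CSF receptor, and Gpnmb, a transmembrane glycoprotein. Csf2rb rose by 2.10 ± 0.10 on the log2 scale, or 4.29-fold (SE, n = 4 per group, adjusted p = 9.4e-05), and Gpnmb by 2.03 ± 0.08, or 4.07-fold (adjusted p = 5.27e-05). The largest falls were those of Aldh1a1, an enzyme that makes retinoic acid, which changed by −2.11 ± 0.08, or 4.30-fold (adjusted p = 4.47e-05), and Krt7, a keratin of simple epithelia, which changed by −1.55 ± 0.11, or 2.93-fold (adjusted p = 0.000545). In mm9 coordinates the probes lie on chromosome 15 at 78181168 to 78181227 for Csf2rb, on chromosome 6 at 49006386 to 49006445 for Gpnmb, on chromosome 19 at 20717764 to 20717823 for Aldh1a1 and on chromosome 15 at 101253718 to 101253777 for Krt7. Whether a probe lies in an exon's coding part or in a UTR was not determined.

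Among the other large rises were those of 3 chemokines, a pair of receptors and several secreted proteins. The chemokine Ccl5 rose by 1.49 ± 0.17 (adjusted p = 0.00396), the chemokine Ccl7 by 1.14 ± 0.09 (adjusted p = 0.00109) and the chemokine Cxcl16 by 1.36 ± 0.26 (adjusted p = 0.0259). Mgp, an inhibitor of calcification found in matrix, rose by 1.61 ± 0.21 (adjusted p = 0.00729), the BMP antagonist Grem1 by 1.24 ± 0.25 (adjusted p = 0.0341), and Slpi, a secreted protease inhibitor, 2.30-fold (adjusted p = 0.000228). Ifitm3, an antiviral membrane protein induced by interferon, rose by 1.14 ± 0.04 (adjusted p = 4.47e-05). The receptor genes Fgfr1 and Gper1 rose 2.29-fold and 2.51-fold, though 1 of 3 Fgfr1 probes had the opposite sign, and Ramp3, which encodes an accessory protein of receptors, rose 2.21-fold. Klhl30, Gem and Angpt1 rose by 1.34, 1.27 and 1.19.

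The other falls included a milk protein, transporters and transcription regulators. Csn3, the kappa-casein of milk, changed by −1.23 ± 0.14 (adjusted p = 0.00396), the drug efflux transporter Abcg2 by −1.30 ± 0.13 (adjusted p = 0.00212), and the transcription factor Gata6 by −1.31 ± 0.11 (adjusted p = 0.00152). The cytokine Il33 changed by −1.14 ± 0.21 (adjusted p = 0.0229), and Mgmt, a DNA repair protein, by −1.33 ± 0.28 (adjusted p = 0.0403). Pde3b, Marcksl1, Wtip, Armcx3, Slc16a6 and Ddah1 changed by −1.39, −1.35, −1.35, −1.16, −1.16 and −1.08. All 28 genes named for their size (15 higher and 13 lower) stood well above background on all 8 arrays. Their R175Q and wild-type values did not overlap, which was a condition for naming them. With the background taken from negative control spots, a correction added after the data were seen, all 28 still passed, and the changes of Mgp and Ramp3 grew to 2.36 and 1.77. With slide as a fixed block 1 of the 28 passed, and with both that background and the slide block 28 did.

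**Figure D1:**
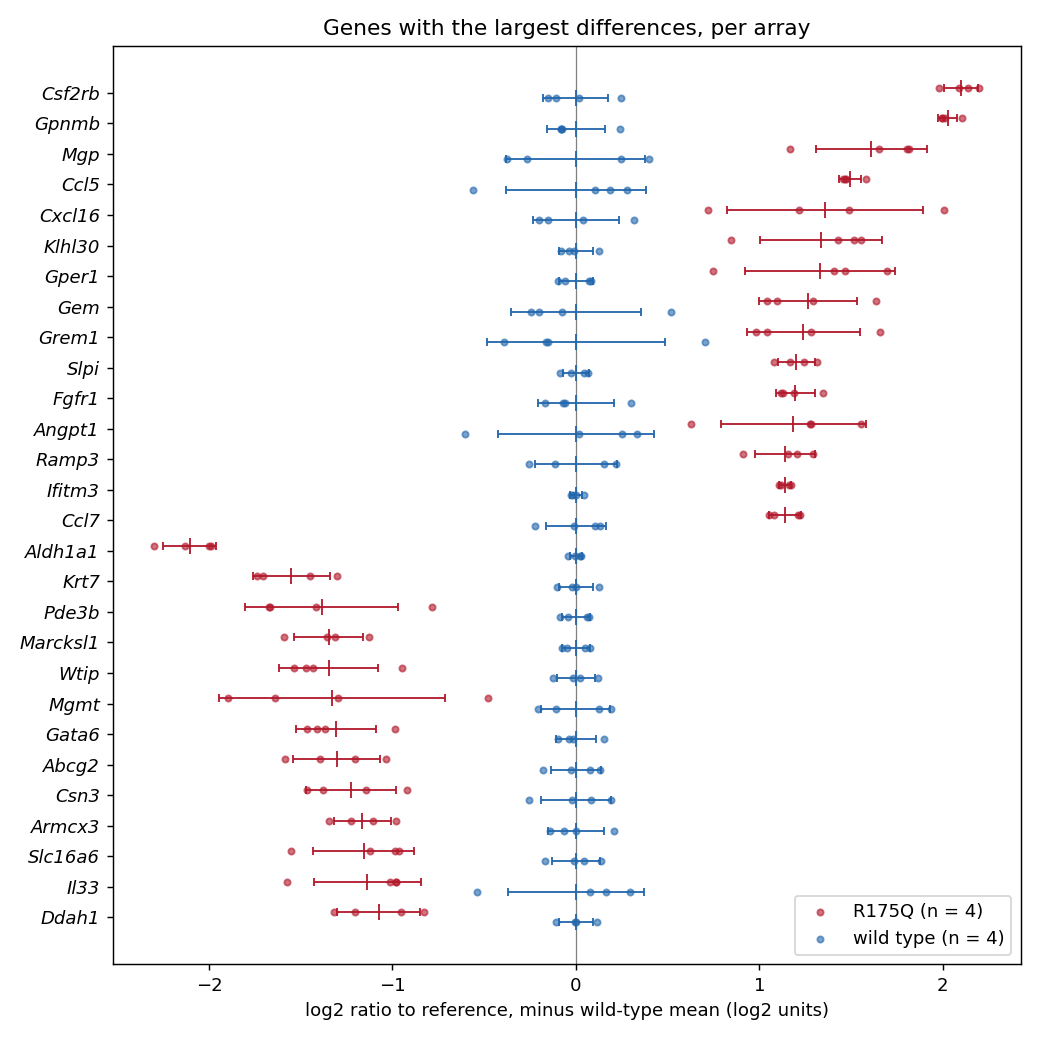
Log2 ratio of sample to reference, less the wild-type mean, on the horizontal axis for each of the 28 genes named for their size. Points are arrays, bars are mean ± SD (n = 4 per group), and the genes were chosen so that the 4 R175Q arrays do not overlap the 4 wild-type arrays.

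The genes named in advance did not pass. Shc1, which encodes ShcA, differed by −0.14 ± 0.07 (adjusted p = 0.371), and since both groups carry a ShcA cDNA, whether its probe at 89233868 to 89233927 on chromosome 3 reads the cDNA was not determined. Erbb2, a receptor tyrosine kinase, differed by −0.16 ± 0.07 (adjusted p = 0.248). Fn1, which encodes fibronectin, differed by 0.91 ± 0.28 (adjusted p = 0.125) and passed with the negative control background, at 0.96 ± 0.26 (adjusted p = 0.0291). The integrin genes Itga5 and Itgb1, whose products together bind fibronectin, differed by 0.10 ± 0.08 (adjusted p = 0.512) and −0.16 ± 0.08 (adjusted p = 0.321). Centring each array on its median in place of loess moved the median of all genes to 0.30 and Shc1, Erbb2 and Itgb1 to 0.28, 0.24 and 0.19. Less that shift the 3 genes stayed negative, at −0.018, −0.066 and −0.11.

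Of 17458 genes tested, 468 were higher and 416 lower in R175Q, with 31 and 14 of them differing by 1 log2 or more. The groups were separated for 2286 genes, or 13.1%, where chance gives 2.86% for a gene taken singly. Genes vary together across arrays, so this gap by itself does not exclude chance. With the same values, a split of the arrays that mixed the groups called 2818 genes. The background level that the planned correction fitted to Cy3 ran from −690 on R175Q replicate 4 to −0.369 on R175Q replicate 3, while the negative control spots had medians of 13.1 to 22.7. With the background taken from those spots, 1532 genes were higher and 1717 lower, and 883 of the 884 calls were kept in direction. With slide as a fixed block the planned correction called 0 genes higher and 1 lower, Aldh1a1 at −2.17 ± 0.07 (limma, adjusted p = 0.0323), with 2176 at an unadjusted p under 0.05. R175Q replicate 1, alone on slide 1, adds nothing to the difference in a fit with that block, which also has less power. With the negative control background and the slide block, 1028 were higher and 1191 lower. Leaving out 1 array moved the counts of higher and lower genes to 188 and 185 without R175Q replicate 1, 173 and 134 without R175Q replicate 2, 309 and 234 without R175Q replicate 3, and 857 and 846 without R175Q replicate 4. They were 151 and 119 without wild-type replicate 1, 209 and 182 without replicate 2, and 214 and 157 without replicate 4.

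**Figure D2:**
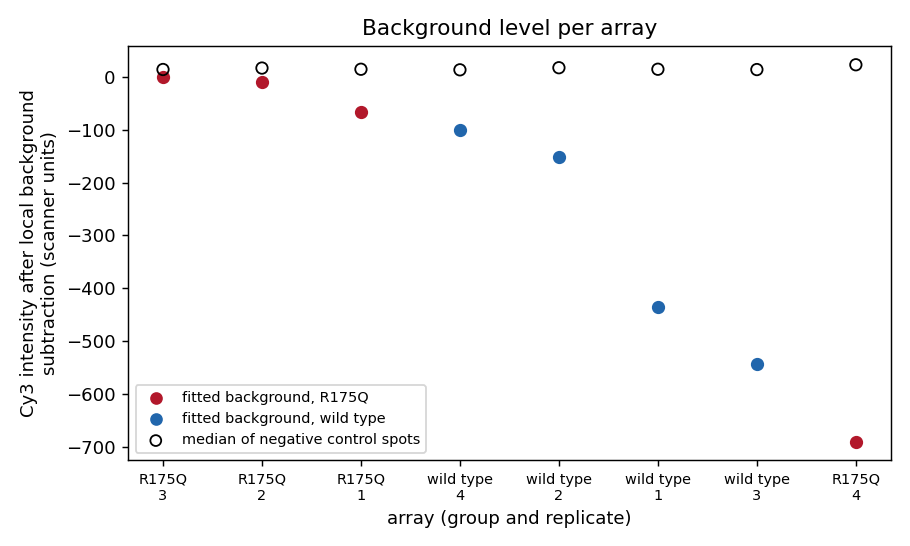
Fitted Cy3 background level in scanner units on the vertical axis for each array, with the median of the negative control spots as open circles. The fitted level ran from −690 to −0.369, and the control medians from 13.1 to 22.7.

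The interferon response and chemokine lists were higher in R175Q by camera at its preset correlation, though most members of each did not pass. Of 21 interferon response genes measured, 9 rose, 0 fell and 12 did not pass, with 10 rises when adjusted over the list alone. Rsad2, an antiviral enzyme, rose by 0.97 ± 0.11, Ifit1, an RNA-binding antiviral protein, by 0.47 ± 0.06, and the transcription factors Irf9 and Irf1 by 0.59 and 0.36. The list mean was 0.28 higher (camera adjusted p = 4.1e-06; adjusted p = 0.57 with an estimated correlation), and within the 3 slides it was 0.03, 0.14 and 0.76. With the negative control background the values within the slides were 0.52, 0.59 and 0.81. Against the other genes the list's planned shift was 0.30, and 0.17 without R175Q replicate 4 (camera adjusted p = 0.039). Of 16 chemokines and cytokines, 4 rose, 1 fell and 11 did not pass, with 5 rises and 1 fall when adjusted over the list alone. Besides Ccl5, Ccl7 and Cxcl16, the chemokine Ccl8 rose by 0.89 ± 0.19, a gene chosen after its value was seen, and the fall was that of Il33. The list mean was 0.33 higher (camera adjusted p = 0.00455; adjusted p = 0.442 with an estimated correlation), at 0.28, 0.58 and 0.20 within the slides. Markers of macrophages and myeloid cells averaged −0.35 (camera adjusted p = 0.453) and of lymphocytes −0.33 (camera adjusted p = 0.546), and 0 of their 11 and 6 measured members passed in limma. Within the slides the planned myeloid means were −0.84, −0.74 and 0.65 and the lymphocyte means −0.86, −0.81 and 0.78. The last of each was on the slide of R175Q replicate 4. Over all arrays the means were −0.08 and −0.04 with the negative control background. Against the other genes the shifts turned to 0.12 and 0.18 with scaling between arrays, and both lists passed as lower with median centring (camera adjusted p = 0.000744 and 0.0109).

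By camera at its preset correlation the hypoxia and glycolysis list was higher and the epithelial list lower, though most members of each did not pass. Of 22 hypoxia and glycolysis genes, 4 rose, 0 fell and 18 did not pass, with 4 rises when adjusted over the list alone. These were Bnip3, a mitochondrial protein of mitophagy (0.89 ± 0.15), P4ha2, a collagen prolyl hydroxylase subunit (0.62 ± 0.13), Pdk1, which inhibits pyruvate dehydrogenase (0.39 ± 0.08), and the glycolytic enzyme Pfkl (0.34 ± 0.07). The list mean was 0.22 higher (camera adjusted p = 3.15e-05; adjusted p = 0.579 with an estimated correlation), at 0.15, 0.03 and 0.60 within the slides. With the negative control background the values within the slides were 0.37, 0.24 and 0.52. Against the other genes the list's planned shift was 0.24, and 0.14 without R175Q replicate 4 (camera adjusted p = 0.039). Of 19 genes of epithelial junctions and keratins, 0 rose, 2 fell and 17 did not pass, with 3 falls when adjusted over the list alone. The falls were those of Krt7 and of Krt19, a keratin of simple epithelia, at −0.41 ± 0.08. The list mean changed by −0.31 (camera adjusted p = 0.0125; adjusted p = 0.382 with an estimated correlation), at −0.37, −0.33 and −0.23 within the slides, and with slide as a fixed block its adjusted p was 0.065. Markers of fibroblasts and pericytes averaged −0.32 (camera adjusted p = 0.758) and 0.25 with the negative control background (camera adjusted p = 0.126). Within the slides their planned means were −1.12, −1.06 and 1.47, the last on the slide of R175Q replicate 4. These markers passed in 6 of 29 alternatives, against the other genes as lower without R175Q replicate 4, at −0.74 (camera adjusted p = 0.0354), and as higher in the other 5, among them the deposited table, at 0.29 (camera adjusted p = 0.0275).

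Across the 25 lists, camera called these 4 with its preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. The fry test asks whether a list's genes move one way on balance, without comparing them with other genes. It called 4 lists: epithelial junctions and keratins (adjusted p = 4.4e-05), chemokines and cytokines (adjusted p = 0.0177), adipocytes (adjusted p = 0.0364) and the Shc family and adaptor partners (adjusted p = 0.0456). Under the negative control background camera called 6 lists with its preset correlation and 0 with an estimated one, and fry called 11. In the 4 lists called as planned it gave 14 rises and 1 fall for interferon response, 7 rises and 1 fall for chemokines, 8 rises for hypoxia and 7 falls for epithelial genes. An exact two-sided permutation test of the list mean per array, whose smallest p is 0.0286, passed for 0 lists after adjustment. It gave 3 lists that smallest p before adjustment, with a lowest adjusted p of 0.238, and for any list to pass after adjustment at least 15 would have had to reach it. Among lists not called as planned, the ErbB list passed in 5 of 29 alternatives, matrix proteases and the Shc family in 3 each, adipocytes in 2, and the luminal and skeletal muscle lists in 1 each.

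**Figure D3:**
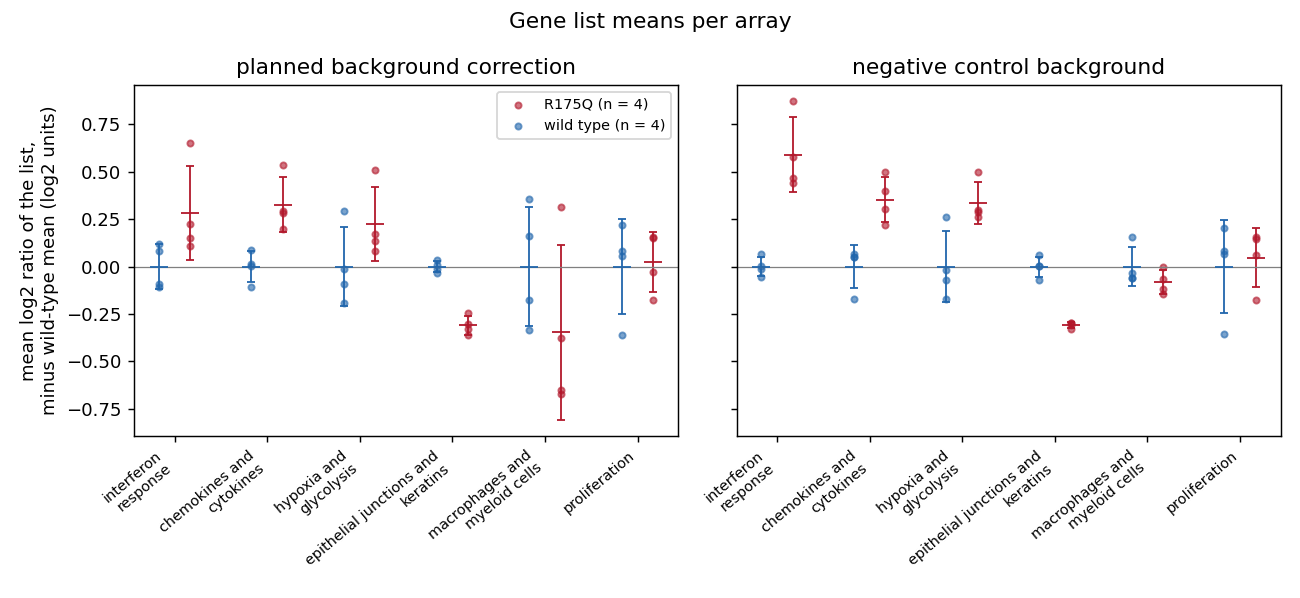
Mean log2 ratio of 6 gene lists, less the wild-type mean, on the vertical axis for each array with the planned background correction (left) and the negative control background (right). Points are arrays and bars are mean ± SD (n = 4 per group), with the interferon list higher in R175Q by 0.28 on the left and 0.59 on the right.

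Adhesion and matrix genes had few members that passed. Of 14 measured genes for fibronectin and integrins, 1 rose, Itgb7, an integrin subunit of leukocytes, by 0.58 ± 0.08, and 13 did not pass (1 rise when adjusted over the list alone). That list's mean was 0.06 and its median −0.007 (camera adjusted p = 0.937). Of 20 focal adhesion genes, 2 rose, Tns1 by 1.01 ± 0.08 and Tns3 by 0.39 ± 0.05, both tensins that link integrins to actin, and 18 did not pass (3 rises and 1 fall when adjusted over the list alone, list mean 0.05, camera adjusted p = 0.371). Of 26 extracellular matrix genes, 3 rose and 23 did not pass (3 rises when adjusted over the list alone). These were Thbs1, an adhesive glycoprotein (0.99 ± 0.15), Col12a1, a collagen chain (0.84 ± 0.14), and Lamb1, a laminin chain (0.52 ± 0.11). Their list mean was −0.10 while camera ranked the list upward (adjusted p = 0.774). The mean turned to 0.17 with the negative control background (camera adjusted p = 0.0326; adjusted p = 0.647 with an estimated correlation), one of 6 alternatives of 29 in which the list passed. Of 19 matrix proteases and inhibitors, Mmp2 rose by 1.11 ± 0.22 and Adamts4 by 0.59 ± 0.06, both proteases, and 17 did not pass (3 rises and 2 falls when adjusted over the list alone, list mean 0.03, camera adjusted p = 0.453). The negative control background gave 3 rises and 3 falls among fibronectin and integrins. Besides Itgb7 these were Fn1 at 0.96 and the integrin subunit genes Itgb5 at 0.20, Itga3 at −0.28, Itga2 at −0.97 and Itgb6, well above background on 6 arrays, at −0.82. It gave 3 rises and 2 falls in focal adhesion, adding the talin gene Tln2 at 0.26, the adaptor Lims1 at −0.32 and the kindlin gene Fermt1 at −0.67, and 8 rises and 2 falls in extracellular matrix. In matrix proteases and inhibitors it gave 5 rises and 1 fall, adding among others the proteases Mmp3 at 0.97 and Plau at 0.44 and the inhibitor Timp3 at 0.51. With the planned correction Itga2, Fermt1 and Plau had stood at 0.05 ± 0.31, −0.05 ± 0.41 and 0.0023 ± 0.24. Fermt1 turned to 0.33 with the scanner's processed ratio.

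Camera called none of the 4 signalling lists. Of 21 genes of ERK pathway output, Etv4, a transcription factor, rose by 0.31 ± 0.05, Spry1, an inhibitor of the pathway, changed by −0.53 ± 0.12, and 19 did not pass. Its mean was −0.04 and its median 0.03 (camera adjusted p = 0.972; 1 rise and 2 falls when adjusted over the list alone). Of 10 ErbB receptors and ligands, 0 rose and 1 fell, the ligand Nrg1 at −0.42 ± 0.06, and 9 did not pass (3 falls when adjusted over the list alone, list mean −0.11, camera adjusted p = 0.177). Of 19 genes of the Shc family and adaptor partners, 0 rose and 3 fell, the adaptor genes Grb7 at −0.61 ± 0.07, Irs1 at −0.69 ± 0.13 and Irs2 at −0.38 ± 0.07, and 16 did not pass (4 falls when adjusted over the list alone, list mean −0.08, camera adjusted p = 0.278). Of 19 TGF-beta pathway genes, 0 rose and 2 fell, the transducer Smad3 at −0.29 ± 0.05 and the matricellular protein Ccn2 at −0.86 ± 0.14, and 17 did not pass. Its mean was −0.03, its median 0.04 and its camera ranking upward (adjusted p = 0.972; 3 rises and 3 falls when adjusted over the list alone). The negative control background gave 3 rises and 4 falls in that list, adding among others the ligand genes Tgfb1 at 0.23, Tgfb3 at 0.52 and Tgfb2 at −0.45 and the target Tgfbi at 0.88. It gave 2 rises and 2 falls in ERK output, adding the inhibitor Spry2 at 0.48 and the target Phlda1 at −0.42, 4 falls in the ErbB list, and 5 falls in the Shc family and partners, adding the adaptor genes Gab1 at −0.36 and Grb14 at −1.09.

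Lists of cell state had few or no members that passed. In the mesenchymal list 2 of 12 genes rose, the transcription factors Twist2 by 0.61 ± 0.10 and Snai1 by 0.37 ± 0.08, and 10 did not pass (3 rises when adjusted over the list alone, list mean 0.10, camera adjusted p = 0.101). That list passed in 12 of 29 alternatives. In antigen presentation 3 of 11 rose, the class I genes H2-D1 by 0.64 ± 0.07 and H2-K1 by 0.36 ± 0.06 and the peptide-loading factor Tapbp by 0.37 ± 0.06, and 8 did not pass (3 rises when adjusted over the list alone). That list's mean was −0.12 and its median −0.39 while camera ranked it upward (adjusted p = 0.29). Under the negative control background its mean turned to 0.15 and its median to 0.08 (camera adjusted p = 0.0547), and the list passed as higher in 5 of 29 alternatives. In the luminal and milk list 1 of 7 fell, Csn3, and 6 did not pass (1 fall when adjusted over the list alone, list mean −0.26, camera adjusted p = 0.72). In stress and heat shock 1 of 14 rose, the chaperone Dnaja1 by 0.37 ± 0.06, and 13 did not pass (3 rises and 1 fall when adjusted over the list alone, list mean 0.12, camera adjusted p = 0.453). In proliferation 0 of 23 passed in limma, also when adjusted over the list alone, with a list mean of 0.03 (camera adjusted p = 0.617) and the cyclin Ccnb1 at 0.28 ± 0.12. The negative control background gave 5 rises in the mesenchymal list, 3 in antigen presentation and 0 calls in proliferation. It gave 1 rise and 2 falls in the luminal list, adding the receptor gene Esr1 at 0.47 and the transcription factor Foxa1 at −0.38, and 3 rises in stress and heat shock, adding the chaperone Hspa5 at 0.42 and the transcription factor Xbp1 at 0.37.

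With the planned correction, markers of other cell types gave 1 call. In adipocytes 1 of 5 genes fell, Fabp4, a fatty acid carrier, at −0.72 ± 0.14, and 4 did not pass (1 fall when adjusted over the list alone, list mean −0.21, camera adjusted p = 0.371). In limma 0 of 7 basal or myoepithelial markers passed (list mean −0.15 with camera ranking it upward, adjusted p = 0.972), 0 of 7 endothelial markers (list mean −0.16, camera adjusted p = 0.972), 0 of 3 skeletal muscle markers (list mean −0.57, camera adjusted p = 0.453) and 0 of 3 red blood cell markers (list mean −0.04, camera adjusted p = 0.972). None of these 4 lists, nor the myeloid and lymphocyte lists, had a member passing when adjusted over the list alone. Of 9 fibroblast and pericyte markers 0 passed, and 1 rose when adjusted over the list alone, with the receptor gene Pdgfrb at 0.66 ± 0.17. The markers gave 10 calls with the negative control background. The 7 rises were those of Pdgfrb, Dcn and Col3a1 (1.18, 0.72 and 0.39), the globin genes Hba-a1 and Hba-a2 (0.42 and 0.39), Vwf (0.84) and Krt17 (0.38), and the 3 falls those of Fabp4, Mrc1 and Adgre1 (−1.02, −0.61 and −0.28). The basal, endothelial, skeletal muscle and red blood cell means turned to 0.013, 0.074, 0.055 and 0.22, and camera called 0 of the 8 marker lists. Over all genes, 3211 had an unadjusted p under 0.05.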

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

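The tests of leukocytes, of slides, of fibroblasts and of the share of epithelial cells were chosen after the results were seen, as was the negative control background, and the tests of splits, of the background level and of R175Q replicate 4 were written before their values were known.

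In 288 sets of 4 arrays, 18 held an array far from the other 3 of its group by Dixon's criterion, and chance gives about 1 in 20 such sets. R175Q replicate 4 stood apart in the fitted Cy3 background level (−690), in Ccl5 (log2 ratio −0.73), Nid1 (−2.70), Itga3 (2.04) and Timp3 (−3.27). R175Q replicate 3 stood apart in Il33 (−0.89), Ccn2 (−1.86), Pdk1 (−0.24), Esr1 (−0.35) and the mean of the fibronectin and integrin list (0.29). Wild-type replicate 3 stood apart in Gpnmb (−1.14), Irs1 (−1.14), Xbp1 (−1.47) and the mean of the stress and heat shock list (0.061). Wild-type replicate 4 stood apart in Tns1 (−1.32), Smad3 (0.43) and its number of spots marked as unreliable (397) and wild-type replicate 1 in Hspa5 (0.16).

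Of the 35 splits of the 8 arrays into 4 and 4, 2 called as many genes as the real split with the planned correction (884), so chance was not excluded. The other one called 2818 genes and set R175Q replicates 1, 2 and 3 with wild-type replicate 4 against the rest, the 4 arrays with the highest fitted Cy3 backgrounds. That split called 0 genes with the negative control background, so its calls depended on the planned correction. With the negative control background only the real split of the 35 called as many genes (3249), and the highest other called 0. That share, 2.86%, is the smallest that 35 splits can give, and it lay under the bound set in advance. Chance is argued against only as far as so few splits allow. The background was chosen after the data were seen, and the splits took no account of slides.

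The planned correction called 884 genes where the negative control background called 3249. An unequally fitted background level was to be counted out if the planned spread in the dimmest of 4 equal groups of genes was under 1.2 times that with the negative control background; the ratio was 1.00, so that bound was met. The bound was misplaced, as seen only afterwards: the planned correction also shrinks dim log2 ratios, with a median size of 0.19 against 0.45 in that group, and with 8 equal groups the spread ratio was 0.69 in the dimmest and 1.59 and 1.92 in the next ones, so this test leaves an unequal fit open. In the brightest of the 8 groups the ratio was 1.00. Without that fit, 3402 genes were called with no background correction and 2936 with the scanner's processed ratio, so the lower count went with the planned correction. Cy3 alone and arrayWeights, both on planned backgrounds, called 2574 and 4897, so the fit was not all that moved the counts. Without R175Q replicate 4 the planned correction called 1703 genes and the negative control background 2467, within the factor of 1.5 set in advance, so that array may account for part of the gap. It also had the lowest fitted Cy3 background, at −690. Its mean correlation with the other R175Q arrays was 0.936 with the planned correction and 0.990 with the negative control background. Leaving it out therefore cannot tell a deviant array from an unequal fit to that array. No biological explanation of a gap between corrections was tested.

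Interferon response and chemokine lists were higher in R175Q. A rise in the R175Q samples shared by the leukocyte markers read on all 8 arrays is weakly argued against. With the negative control background, 12 myeloid and lymphocyte markers read on all 8 arrays averaged −0.056 ± 0.076 (SE), a mean plus 2 SE of 0.097. With the planned correction they averaged −0.29 ± 0.11. These SEs are taken over markers, not arrays, so they do not measure the spread between samples. The planned means of the myeloid and lymphocyte lists also differed in sign between slides. They were 0.65 and 0.78 on the slide of R175Q replicate 4 and negative on the others. The markers also went both ways with the negative control background, Cd68 at 0.54 ± 0.25 (limma, adjusted p = 0.167) and Mrc1 at −0.61. Itgb7, an integrin subunit of leukocytes outside this set, rose by 0.58 as planned, so leukocytes are not excluded. With slide as a fixed block both lists kept a camera adjusted p of at most 0.00132. That alone does not settle a part of slides, since at its preset correlation camera takes the genes of a list as nearly independent. Within the 3 slides with both groups the chemokine mean was 0.28, 0.58 and 0.20 higher in R175Q. The interferon mean was 0.03, 0.14 and 0.76 higher with the planned correction, the last on the slide of R175Q replicate 4. With the negative control background it was 0.52, 0.59 and 0.81 higher. A level shared by all arrays of a slide would not give such differences, though with the planned correction those of interferon were small but for the last. Over all alternatives the camera adjusted p ranged from 2.09e-12 to 0.57 for interferon response and from 7.45e-05 to 0.442 for chemokines. An effect of R175Q, a difference between the derived cell populations and other differences in culture stay open as untested, and with an estimated correlation neither list passed. Without R175Q replicate 4 the interferon shift was 0.17 in place of 0.30 (camera adjusted p = 0.039).

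The epithelial list was lower and several matrix genes were higher in R175Q, but at an unchanged shift of −0.29 the list's camera adjusted p of 0.0125 rose to 0.382 with an estimated correlation and to 0.065 with slide as a fixed block. The correlation estimated for this list was −0.047, so its genes varying together did not bring that first rise. By fry the list's adjusted p was 4.4e-05, and its mean was lower within each slide, at −0.37, −0.33 and −0.23. Whether the share of epithelial cells was lower was not settled. The test asked only whether markers of other cell types rose alike, which they would not if fibroblasts alone took the place of epithelial cells. With the negative control background fibroblast markers exceeded leukocyte markers by 0.41 ± 0.19 (SE over markers, not arrays), 0.0287 to 0.787 at 2 SE. That argues narrowly against an even rise of the other cell types, and only with that background. With the planned correction the markers did not move apart by more than their spread (0.077 ± 0.19). More fibroblasts in the R175Q samples cannot be told apart from a change within the cells, because 7 fibroblast markers read on all 8 arrays averaged 0.35 ± 0.17 (SE) with the negative control background, 0.00499 to 0.699 at 2 SE, which spans the bound of 0.2, and −0.21 ± 0.16 with the planned correction. With the negative control background Pdgfrb stood at 1.18, Dcn at 0.72, Col3a1, also in the matrix list, at 0.39 and the other 4 between −0.11 and 0.24, where the planned correction gave 0.66, −0.042, −0.28 and between −0.56 and −0.35. An effect of R175Q on the cells stays open as untested, and the labels, which give a cultured line, also call the material microdissected.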

How the results depend on the processing

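The negative control background, alone and with slide as a fixed block, and scan day as a fixed block were chosen after the results were seen; the other alternatives were not. The counts of 468 higher and 416 lower genes stayed within 1.5 times under no filter (418 and 382), the filter on all 8 arrays (484 and 434), every probe on its own (483 and 429), the mean of probes (383 and 333), and the trend and robust fit (441 and 408). Quantile normalization of brightness leaves log ratios as they are, so its 468 and 416 test nothing. They were 1700 and 1702 with no background correction, 1467 and 1469 with the scanner's processed ratio, 1391 and 1183 from Cy3 alone, 1596 and 1611 in the deposited table, 2216 and 2681 with arrayWeights, and 1532 and 1717 with the negative control background. They were 61 and 54 with scaling between arrays, 91 and 57 with replicate number as a block, 0 and 1 with slide as a fixed block, 365 and 271 with slide as a random block, 53 and 43 with scan day, and 1028 and 1191 with the negative control background and the slide block. Median centring shifted the median of all genes to 0.30, and limma then called 0 and 0, with 304 at an unadjusted p under 0.05. Leaving out 1 array gave 151 to 857 higher and 119 to 846 lower, moving by over 1.5 times without R175Q replicate 1 (188 and 185), R175Q replicate 2 (173 and 134), R175Q replicate 3 (309 and 234), R175Q replicate 4 (857 and 846), wild-type replicate 1 (151 and 119), wild-type replicate 2 (209 and 182) and wild-type replicate 4 (214 and 157). With fewer arrays a fit has less power, as it has with slide as a fixed block, where R175Q replicate 1, alone on slide 1, does not count. The cause of the other moves was not tested. Replicate numbers were not taken as pairs, since not every residual correlation of same-numbered arrays exceeded 0.1: they were 0.34, 0.43, −0.44 and −0.85 as planned, with 1 of 4 R175Q arrays closest to its own number, and 0.34, 0.017, 0.48 and 0.048 with the negative control background, with 2 of 4.

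Camera called 4 lists as planned, 11 with no background correction, 9 with the processed ratio, 9 with median centring, 11 from Cy3 alone, 8 in the deposited table, 9 with the negative control background and the slide block, 0 with an estimated correlation, and 4 to 5 without 1 array. The epithelial list lost its call with scaling (−0.41, adjusted p = 0.111) and with slide as a fixed block (−0.29, adjusted p = 0.065). The chemokine list lost it with scaling (0.27, adjusted p = 0.143), no filter (0.16, adjusted p = 0.0932) and arrayWeights (0.30, adjusted p = 0.087). With an estimated correlation all 4 lists lost it at shifts of −0.29 for epithelial genes, 0.35 for chemokines, 0.30 for interferon response and 0.24 for hypoxia, and with fry the last 2 did (adjusted p = 0.0739 and 0.102). The exact permutation test of list means could pass only with at least 15 lists at its smallest p, so its 0 passes say nothing of stability. Without R175Q replicate 4 the interferon shift fell from 0.30 to 0.17 and the hypoxia shift from 0.24 to 0.14, both still passing (adjusted p = 0.039). Of 111 named genes, slide as a fixed block left 47 on the same side of the threshold in the same direction, scaling 47, median centring 34, and the negative control background 68, with 39 newly passing in the same direction, many of them named because they did. Median centring turned 17 genes, of which 15 stayed on their side of the median of all genes (0.30), so that shared shift accounts for those turns.

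The values that turned sign, on the log2 scale and less the mean of the other genes for lists, were as follows, and apart from the shared shift under median centring the cause was not tested. With no background correction, the lists turned to integrin −0.014, extracellular matrix 0.19, ERK 0.032, antigen presentation 0.17, basal 0.0078, fibroblasts 0.30, endothelial 0.10, skeletal muscle 0.16 and red cell 0.25, and the genes to Dcn 0.74, Col3a1 0.40, Hba-a1 0.45 and Itga2 −0.89. With the scanner's processed ratio, the lists turned to integrin −0.11, extracellular matrix 0.24, ERK 0.054, antigen presentation 0.20, basal 0.0026, fibroblasts 0.38, endothelial 0.12, skeletal muscle 0.26 and red cell 0.27, and the genes to Dcn 0.90, Col3a1 0.51, Hba-a1 0.53, Itga2 −0.87 and Fermt1 0.33. With median centring, the lists turned to ERK 0.048 and TGF-beta 0.088, and the genes to Shc1 0.28, Erbb2 0.24, Itgb1 0.19, Egfr 0.14, Hbegf 0.010, Irs2 0.020, Krt8 0.12, Smad3 0.11, Mrc1 0.20, Dcn 0.36, Col3a1 0.12, Tgfa 0.32, Hba-a1 0.25, Itga3 0.14, Lims1 0.046, Fermt1 0.11 and Foxa1 0.12. With scaling between arrays, the lists turned to extracellular matrix 0.43, ERK 0.043, antigen presentation 0.48, basal 0.14, fibroblasts 0.75, endothelial 0.22, myeloid 0.12, lymphocytes 0.18, skeletal muscle 0.12 and red cell 0.29, and the genes to Ifit2 0.014, Nid1 0.26, Adgre1 0.13, Dcn 1.27, Col3a1 1.15, Hba-a1 0.38, Itga2 −0.25 and Tgfb2 0.099. From Cy3 alone, the lists turned to extracellular matrix 0.14, ERK 0.027, antigen presentation 0.17, basal 0.013, fibroblasts 0.22, endothelial 0.065, lymphocytes 0.0023, skeletal muscle 0.060 and red cell 0.18, and the genes to Dcn 0.51, Col3a1 0.23, Hba-a1 0.36 and Itga2 −0.43. In the deposited table, the lists turned to integrin −0.0025, extracellular matrix 0.23, ERK 0.042, antigen presentation 0.22, basal 0.031, fibroblasts 0.29, endothelial 0.11, lymphocytes 0.037, skeletal muscle 0.18 and red cell 0.20, and the genes to Dcn 0.69, Col3a1 0.44, Hba-a1 0.39 and Itga2 −0.74. With no filter, the lists turned to matrix proteases −0.014, mesenchymal −0.067 and red cell 0.016, and the genes to Esr1 −0.37. With every probe on its own, the lists turned to TGF-beta 0.0046. With arrayWeights, the lists turned to matrix proteases −0.033 and TGF-beta 0.016, and the genes to Mrc1 0.17, Tgfa 0.19, Foxc2 −0.36, Hba-a2 −0.18, Fermt1 0.24, Plau −0.27 and Spry2 −0.042. With slide as a fixed block, the lists turned to ERK 0.032 and proliferation −0.023, and the genes to Dcn 0.040, Hba-a2 −0.051 and Fermt1 0.12. With slide as a random block, the genes turned to Itga2 −0.0067. With the negative control background, the lists turned to integrin −0.024, extracellular matrix 0.18, ERK 0.032, antigen presentation 0.16, basal 0.024, fibroblasts 0.26, endothelial 0.084, skeletal muscle 0.065 and red cell 0.23, and the genes to Dcn 0.72, Col3a1 0.39, Hba-a1 0.42 and Itga2 −0.97. With that background and the slide block, the lists turned to integrin −0.00026, extracellular matrix 0.20, ERK 0.11, proliferation −0.0068, antigen presentation 0.20, basal 0.017, fibroblasts 0.29, endothelial 0.073, skeletal muscle 0.097 and red cell 0.19, and the genes to Dcn 0.82, Col3a1 0.43, Hba-a1 0.37 and Itga2 −0.95. With scan day as a fixed block, the lists turned to ERK 0.021 and proliferation −0.0073, and the genes to Dcn 0.073, Hba-a2 −0.032 and Fermt1 0.056. Leaving out 1 array gave ranges that cross 0 for ERK −0.075 to 0.061, Dcn −0.42 to 0.15, Hba-a2 −0.17 to 0.14, Fermt1 −0.38 to 0.26, red cell −0.14 to 0.079, Itga2 −0.24 to 0.26, matrix proteases −0.036 to 0.13, Tgfa −0.14 to 0.18, Foxc2 −0.26 to 0.14, Plau −0.19 to 0.12, extracellular matrix −0.27 to 0.016, antigen presentation −0.33 to 0.0092, Hba-a1 −0.31 to 0.073, proliferation −0.071 to 0.12, TGF-beta −0.043 to 0.014 and Mrc1 −0.43 to 0.30.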

Other observations

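All tests in this part were chosen after the results were seen. With the background taken from negative control spots, matrix and mesenchymal genes had more calls in R175Q, as did all genes (884 as planned, 3249 with that background), so the gain was not specific to them. Of 26 extracellular matrix genes 8 rose, among them Col6a3, a collagen chain, by 1.23 ± 0.09 and Thbs1 by 1.16 ± 0.14, 2 fell, the collagen cross-linking enzyme Loxl2 at −1.10 ± 0.10 and the basement membrane protein Nid1 at −0.56 ± 0.13, and 16 did not pass. The list mean was 0.17 higher (camera adjusted p = 0.0326; adjusted p = 0.647 with an estimated correlation). Of 12 mesenchymal genes 5 rose, namely Foxc2, Twist2, S100a4, Snai1 and Zeb1, by 0.73, 0.68, 0.49, 0.40 and 0.28, 0 fell and 7 did not pass. With the planned correction Foxc2 stood at 0.0088 ± 0.31, and at −0.26 without R175Q replicate 4. The mesenchymal genes averaged 0.24 higher (camera adjusted p = 0.015, and 0.583 with an estimated correlation). Fibroblast markers moved with them, with Pdgfrb at 1.18, Dcn at 0.72 and Col3a1 at 0.39 passing and a list mean of 0.25 (camera adjusted p = 0.126), and more fibroblasts in the R175Q samples were not excluded.

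With the same background, 4 of 10 ErbB receptors and ligands fell: the receptor gene Egfr at −0.25 ± 0.06, and the ligand genes Hbegf at −0.41 ± 0.11, Nrg1 at −0.42 ± 0.07 and Tgfa at −0.25 ± 0.06. The list mean was −0.17 (camera adjusted p = 0.0547). In the interferon response 14 of 21 genes rose and 1 fell, Ifit2 at −0.50 ± 0.12, and the list mean was 0.59 higher (camera adjusted p = 4.69e-10; adjusted p = 0.561 with an estimated correlation). Among 11 myeloid markers the macrophage genes Mrc1 and Adgre1 fell, at −0.61 ± 0.09 and −0.28 ± 0.08, and 9 did not pass, with Cd68 at 0.54 ± 0.25. With the planned correction Mrc1 stood at −0.12 ± 0.46, and at 0.30 without R175Q replicate 4. Adgre1 was well above background on 6 arrays.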
